A study of Oryza sativa with 20 samples.

How the data were processed

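Small RNA was profiled in the lamina joint and the blade of the first complete leaf of rice (Oryza sativa) seedlings at 5 stages. Per the labels' protocols, seedlings were grown in water under a cycle of light and dark, and tissue was collected on days 4, 5, 6, 7 and 9 after germination. The labels do not say which day is which stage, so stages are named S1 to S5 only. Total RNA was extracted with TRIzol and the libraries were made by a sequencing company, per the labels' protocols. The authors deposited a file of whole-number counts per tag for each library, not normalised. CASAVA and the genome build IRGSP-1.0 are named in the submitters' processing notes. The aligner, the miRNA annotation, the treatment of reads that match several miRNAs and the counting tool are not given in the sources used here. Mature miRNAs of a family can differ by few bases, so tags of near-identical sequence can share or divide reads. Of the 484 tags with any count, 18 repeated the counts of another tag in all 20 libraries. Removing them left 299 tags tested, as before. The repeats thus lay under the filter on low counts and do not show that tested tags shared reads.

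Groups and replicate numbers were taken from the sample titles, 2 libraries for each of 10 groups. Nothing in the labels says that replicates came from separate batches of plants, so p-values measure only the spread between these libraries, which may be technical. Total counts per library lay between 194799 and 1169330. Of the counts of each library, at least 99.9% fell in the tested tags. Where a group had no count for a tag, folds were computed against 3 counts over the group and written as a lower bound. Where it had few counts, the ratio of summed counts scaled by effective library size was given with an exact 95% binomial interval. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

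The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the deposited counts. TMM factors scaled the libraries, and filterByExpr with a minimum count of 10 and a minimum total of 15 removed low tags, leaving 299. A design with a mean for each of the 10 groups was fitted to all 20 libraries, which left 10 residual degrees of freedom. Contrasts gave lamina joint minus blade averaged over stages and at each stage, S5 minus S1 in each tissue, and the difference between those changes. F tests on 4 contrasts tested for any difference between stages and for tissue by stage. Tests were two-sided, Benjamini-Hochberg adjustment ran over the tested tags, and the threshold was 0.05. Standard errors were derived from the F statistic of each contrast. Levels are CPM on effective library sizes, and principal components used log2 CPM with a prior count of 2. Expected overlaps are the product of the list sizes divided by 299. The lists share each tag's abundance and spread, so tags measured well can be called in both. These products are therefore low references. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

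The tests, the rule for named tags and most alternatives were fixed before the data were examined. The rule took, for each contrast over stages or tissues, up to 12 tags per direction with the largest fold change among those past the threshold with a mean of at least 10 CPM in the libraries of the contrast. For the difference between tissues in the S1 to S5 change it took the 10 with the smallest p. The rule also asked for 1 tag per miRNA family, which could not be applied without names. The files do not pair tags with miRNA names, so at most 2 tags per direction and comparison are printed, in the order of the rule. Lists of miRNA families fixed beforehand, and their set tests, could not be run for the same reason.

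The fits were tested on simulated counts, in 10 simulations for each contrast tested. Counts were drawn from the mean of each tag over all 20 libraries and from the sizes of the real libraries. Simulated libraries therefore held no stage or tissue differences except in the tags that were changed. In each, 60 tags were changed by 2-fold or 4-fold, as many up as down. The recovered shares and false calls thus do not cover unbalanced changes or a rising share of the most abundant tag. The changed set was kept small because only 277 to 290 simulated tags passed the filter. For the average difference between tissues 74.7% of 2-fold and 94.0% of 4-fold changes were recovered, and 5.9% of calls were false. For S5 minus S1 in the lamina joint, 4.7% and 36.0% were recovered, with 1.6% false calls. For the tissues at S5 the recovered shares were 4.7% and 38.3%, with 3.0% false calls. For the difference between tissues in the S1 to S5 change they were 0% and 7.0%, with 0% false calls.

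The alternatives were DESeq2 size factors, total counts or upper quartile factors as the scaling, no filter or a mean of at least 10 CPM, DESeq2 1.42.0, limma 3.58.1 with voom, robust estimation, the replicate number as a block, merging of identical tags, fits to fewer libraries, an additive model, and leaving out each library in turn. Added after the data were seen were fits without the second S1 library of both tissues and fits without the most abundant tag.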

Results

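MicroRNAs are small RNAs that guide the silencing of matching transcripts. Small RNA was sequenced from the lamina joint and the blade of the first complete leaf of rice seedlings at 5 developmental stages, S1 to S5. The lamina joint is the hinge between leaf sheath and blade, and its bending sets the leaf angle. Each of the 10 combinations of tissue and stage had 2 libraries, which made 20 libraries in all. The count files listed their entries as numbered tags and did not pair them with miRNA names, so tags are described here by number, abundance, tissue and stage. Library totals lay between 194799 and 1169330 counts, with a median of 499884. Between 316 and 378 tags were detected per library, 232 tags were detected in all 20 libraries, 484 had a count in at least 1 library, and 201 listed tags had none. A total of 299 tags passed the filter on low counts and entered the tests.

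A few tags held most of the counts. The most abundant tag took on average 24.4% of a library and the 10 most abundant together 77.5%. The share of the most abundant tag was 20.5% ± 11.7 (SD, n = 2) in lamina joint S1 and 39.3% ± 1.42 (SD, n = 2) in lamina joint S5. In the blade it was 21.2% ± 1.23 (SD, n = 2) at S1 and 40.8% ± 0.470 (SD, n = 2) at S5. The replicates of lamina joint S1 were far apart in this share, at 12.3% (exact 95% binomial interval 12.2 to 12.4) and 28.8% (28.6 to 29.0). No replicate pair agreed within sampling noise (chi-square between 37.7 and 247 per degree of freedom), so no pair was counted as 1 library. This says nothing about whether replicates came from separate plants. Spearman correlations between replicates, taken across tags, ranged from 0.848 in lamina joint S1 to 0.958 in lamina joint S2.

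Stage was the main axis of variation among the libraries. The leading principal component held 51.5% of the variance and ordered the group means from S1 to S5 in both tissues. Its mean was -18.15 ± 4.73 (SD, n = 2) in lamina joint S1 and 18.77 ± 1.04 (SD, n = 2) in lamina joint S5. In the blade the corresponding means were -13.43 ± 0.19 (SD, n = 2) and 21.90 ± 2.65 (SD, n = 2). At each stage both lamina joint libraries had lower scores on this component than both blade libraries. The next component held 12% of the variance, and along it the lamina joint S1 replicates stood apart, at 8.47 and 18.11.

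**Figure D1:**
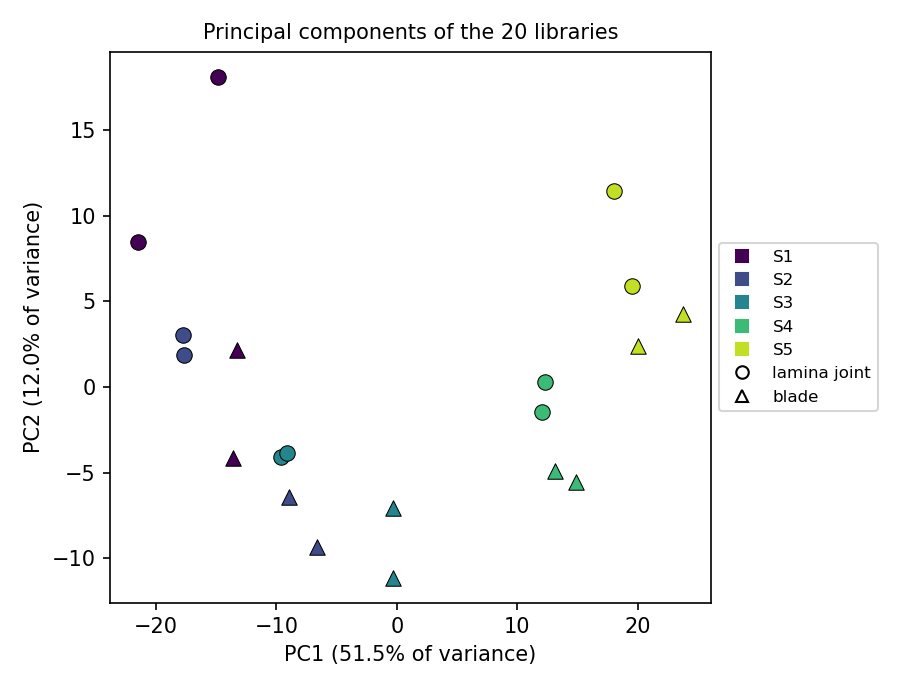
Scores of the 20 libraries on the leading principal components of log2 normalised counts, PC1 (51.5% of variance) on the x axis and PC2 (12%) on the y axis; colour gives the stage, circles are lamina joint and triangles blade. Libraries run from S1 at low PC1 to S5 at high PC1 in both tissues.

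The change of miRNA tags over development was examined within each tissue. In the lamina joint, 155 of the 299 tags differed between stages in an F test on 4 contrasts. Of these tags, 53 had their highest mean at S5, 40 at S1, 34 at S4, 16 at S3 and 12 at S2. The means of 15 tags rose at each step from S1 to S5 and those of 17 fell at each step, where chance orderings would give 0.833% for either course. Chance orderings are a loose reference, since these tags were picked for stage differences in the same libraries and tags do not vary independently. The largest step lay between S3 and S4 for 64 tags. In the blade, 130 tags differed between stages, with the highest mean at S1 for 40, at S5 for 48 and at the 3 middle stages for the rest. A steady rise was seen for 29 blade tags and a steady fall for 25. The largest step lay between S3 and S4 for 57 blade tags.

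In the lamina joint, 132 tags differed between S5 and S1, and 72 of them were higher at S5 and 60 lower. The median fitted change was 2.75 on the log2 scale among the tags that rose and -2.91 among those that fell, or 2.75 and -2.66 with the 9 tags at 0 counts in a whole group set to their bound. Tag_235 had no count in either S1 library and 227 ± 138 normalised CPM (SD, n = 2) at S5, which made it at least 54.5-fold higher (edgeR adjusted p = 1.25e-05). That bound sets S5 against a floor of 3 counts over the S1 group and leaves out the counting error at S5; the exact 95% counting interval of the ratio began at 43.3. Tag_243 went from 1 count at S1 to 291 counts at S5, a ratio of 602 (95% counting interval 107 to 23856; edgeR adjusted p = 2.12e-05). Among the tags that fell, tag_221 had 88 counts at S1 and none at S5 and was at least 14.2-fold lower against that floor (95% counting interval of the ratio up to 0.0886; edgeR adjusted p = 0.00015). Tag_257 fell from 768 ± 19.2 CPM (SD, n = 2) at S1 to 3.78 ± 5.34 CPM (SD, n = 2) at S5, where 1 count was left. Its ratio of S5 to S1 was 0.00319 (95% counting interval 8.06e-05 to 0.0178; edgeR adjusted p = 4.71e-05). Of the 10 most abundant tags, 7 were higher at S5, 0 were lower and 3 did not pass the threshold. Scaling by total counts gave 5 higher and 3 lower among those 10, and 48 higher against 99 lower among 147 tags in all.

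In the blade, 146 tags differed between S5 and S1, of which 71 were higher at S5 and 75 lower. The median fitted change was 2.32 on the log2 scale among the tags that rose and -2.77 among those that fell, or 2.32 and -2.74 with 3 tags set to their bound in the same way. Tag_129 had 2 counts at S1 and 412 at S5, a ratio of 151 (95% counting interval 41.5 to 1249; edgeR adjusted p = 5.62e-05), although its S5 replicates were far apart at 524 and 89.2 CPM. Tag_656 had no count at S1 and 26.0 ± 9.12 CPM (SD, n = 2) at S5, at least 9.03-fold higher against that floor (95% counting interval from 6.98; edgeR adjusted p = 0.00601). Its adjusted p rose to 0.0519 without the first blade S1 library, where the fitted change was 6.76 ± 2.39 (log2, SE), against 6.76 ± 1.56 with it, values that depend on the prior count. Tag_195 fell from 142 ± 34.4 CPM (SD, n = 2) to 1 count at S5, a ratio of 0.00463 (95% counting interval 0.000117 to 0.0262; edgeR adjusted p = 4.87e-05). Tag_257 fell in the blade too, from 799 ± 6.28 to 5.50 ± 7.77 CPM (SD, n = 2), a ratio of 0.0077 (95% counting interval 0.00351 to 0.0147; edgeR adjusted p = 1.98e-05). Of the 10 most abundant tags, 4 were higher at S5 and 0 lower. With scaling by total counts these became 2 higher and 3 lower, and the tags in all 45 higher and 115 lower of 160.

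The S1 to S5 changes of the tissues overlapped. Among the 299 tags, 51 rose in both tissues, against 17.1 for independent lists, and 45 fell in both, against 15.1. No tag fell in the lamina joint and rose in the blade, and 4 tags, among them tag_116, rose in the lamina joint and fell in the blade. Across tags, which are not independent replicates, the fitted changes in the tissues had a Pearson correlation of 0.800 and a Spearman correlation of 0.805. The tissues share no library, so the overlap does not come from shared control libraries. Both lists do come from the same fit, and tags measured well can be called in both, so 17.1 and 15.1 are low references. That does not by itself favour the same direction, which 96 of the 100 tags called in both tissues took. Deviations of the S1 replicates did correlate between the tissues (0.564). Whether a condition common to the S1 libraries adds to the overlap was not tested. Scaling by total counts gave 32 tags that rose in both tissues, against 7.22 for independent lists, and 86 that fell in both, against 38.1. It left 2 tags that rose in the lamina joint and fell in the blade.

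**Figure D2:**
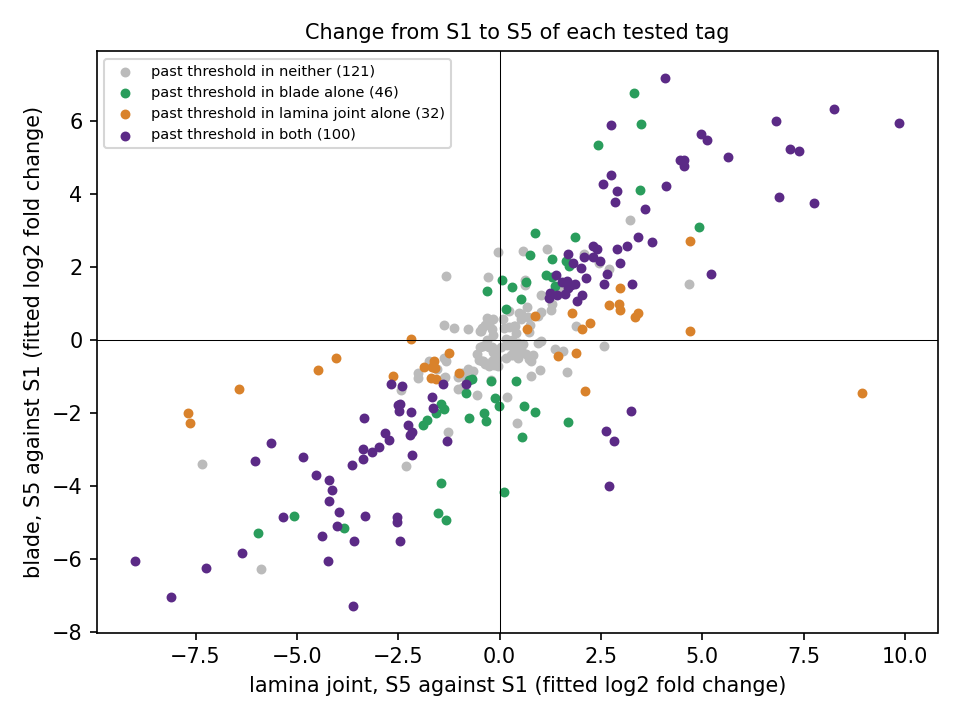
Fitted log2 change from S1 to S5 of each of the 299 tested tags in lamina joint (x axis) and blade (y axis); colour gives the tissues in which the tag passed the threshold. Of the 100 tags past it in both tissues, 96 changed in the same direction, and the other 4 rose in lamina joint and fell in blade.

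The tissues were then compared with each other. Averaged over the 5 stages, 82 tags differed between lamina joint and blade, 33 higher in the lamina joint and 49 lower (upper quartile factors 38 and 37). The median fitted difference was 1.29 on the log2 scale among the higher tags and -1.05 among the lower ones. For 50 of the 82 tags the sign of the fitted difference was the same at all 5 stages. Tag_219 was higher in the lamina joint by 2.93 ± 0.36 (log2, SE; edgeR adjusted p = 4.26e-05), with 228 ± 20.2 CPM (SD, n = 2) against 11.7 ± 2.92 CPM (SD, n = 2) at S1. By S5 it had 9.14 ± 2.25 against 0.772 ± 1.09 CPM (SD, n = 2), from few counts. Tag_134 was higher by 2.62 ± 0.55 (log2, SE; edgeR adjusted p = 0.00331) and reached 1496 ± 298 CPM (SD, n = 2) in lamina joint S5 against 76.7 ± 20.4 CPM (SD, n = 2) in blade S5. At S3 its fitted difference had the other sign, with 4.38 ± 3.38 CPM (SD, n = 2) in the lamina joint and 10.1 ± 3.35 CPM (SD, n = 2) in the blade, and S5 was the only stage at which it passed the threshold by itself (edgeR adjusted p = 0.0101). Tag_227 had a fitted difference of -3.24 ± 0.24 (log2, SE; edgeR adjusted p = 3.74e-07). It had 159 ± 79.7 CPM (SD, n = 2) in lamina joint S4 and 1226 ± 415 CPM (SD, n = 2) in blade S4. The gap narrowed from 8.52 ± 5.03 against 221 ± 90.7 CPM (SD, n = 2) at S1 to 294 ± 118 against 767 ± 20.9 CPM (SD, n = 2) at S5. Tag_227 also passed the F test of tissue by stage (edgeR adjusted p = 0.0368). In the test of the difference between S1 to S5 changes its edgeR adjusted p was 0.0211. Tag_148 had a fitted difference of -2.60 ± 0.30 (log2, SE; edgeR adjusted p = 2.67e-05), with 12.2 ± 0.163 CPM (SD, n = 2) in lamina joint S2 and 195 ± 40.3 CPM (SD, n = 2) in blade S2. Its gap was smaller at S4, with 15.9 ± 11.9 against 32.1 ± 2.58 CPM (SD, n = 2), and at S5, with 18.5 ± 5.89 against 35.9 ± 2.75 CPM (SD, n = 2). Among the 10 most abundant tags, 1 was higher in the lamina joint and 4 were lower (upper quartile factors 2 and 1).

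Stage by stage, the tags that differed were mostly lower in the lamina joint than in the blade at S2 and S3 and mostly higher at S5. At S1, 23 tags differed, 9 higher in the lamina joint and 14 lower (DESeq2 size factors 11 and 10, upper quartile factors 10 and 10). At S2, 46 tags differed, 9 higher and 37 lower (upper quartile factors 11 and 23, total counts without the most abundant tag 12 and 23). At S3, 0 tags were higher and 7 lower (DESeq2 size factors or upper quartile factors 1 and 6, total counts 2 and 5, or 3 and 5 without the most abundant tag). At S5, 12 tags differed, 11 higher and 1 lower (total counts without the most abundant tag 8 and 2). At S4, 3 tags passed the threshold, 2 higher and 1 lower (DESeq2 size factors 1 and 1; total counts, or TMM without the most abundant tag, 4 and 1; limma-voom 4 and 6; DESeq2 7 and 6; the 4 libraries of the stage alone 14 and 7; no filter 22 and 3). Over all settings other than leaving out a single library, the counts ran from 1 to 35 at S1, 34 to 56 at S2, 6 to 20 at S3, 2 to 25 at S4 and 3 to 26 at S5. The 3 tags at S4 are named here after their values were seen. Tag_243 had 307 ± 38.0 CPM (SD, n = 2) in the lamina joint and 8.67 ± 3.03 CPM (SD, n = 2) in the blade (edgeR adjusted p = 0.00409). Tag_059 had 1862 ± 358 CPM (SD, n = 2) against 311 ± 38.7 CPM (SD, n = 2), with an edgeR adjusted p of 0.0475. Tag_227, with the S4 values given above, was the lower tag (edgeR adjusted p = 0.0044). The S1 and S2 lists shared 5 tags that were higher in the lamina joint, against 0.271 for independent lists, and 8 that were lower, against 1.73. The S2 and S3 lists shared 7 lower tags, against 0.866. The S5 list shared 0 tags in the same direction with the S1 and S3 lists, 1 lower tag with S2 and 1 higher tag with S4, and 1 tag had opposite directions at S1 and S5 and 1 at S2 and S5. These counts depended on single libraries: the S1 count was 13 without either blade S1 library, the S2 count 21 to 30 without a lamina joint S2, blade S2 or blade S4 library, the S4 count 6 without the first lamina joint S1 library and 1 without the first lamina joint S4 or first blade S4 library, and the S5 count 1 to 5 without a library of S5. The S3 count was 13 and 15 without a lamina joint S1 library and 0 to 4 without any library of lamina joint S2 or S3 or of blade S1, S4 or S5, the first lamina joint S4 library or the second blade S3 library.

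Whether the change over the stages differed between the tissues was tested directly. The F test of tissue by stage gave 17 tags, and the difference between the S1 to S5 changes also gave 17 tags, of which 12 were shared with the F test. In 15 of these 17 the lamina joint change was the higher, and in 2 the lower (DESeq2 size factors 8 and 3, upper quartile factors 9 and 4). Within the 17, 5 tags rose in the lamina joint and did not pass the threshold in the blade, 4 rose in the lamina joint and fell in the blade, and 3 fell in the blade and did not pass in the lamina joint. Tag_243 rose in the lamina joint, as given above, and had 7 counts at S1, all in the first library, and 3 at S5 in the blade, a ratio of 0.314 (95% counting interval 0.0523 to 1.37). The fitted difference was 10.39 ± 1.58 (log2, SE; edgeR adjusted p = 0.00243), a value that depends on the prior count because the lamina joint had 1 count at S1. Without the first blade S1 library, which leaves no count in blade S1, it was 5.54 ± 83.27 (log2, SE) and did not pass the threshold (edgeR adjusted p = 1.00). Tag_116 rose in the lamina joint from 4 to 12 counts, a ratio of 6.21 (95% counting interval 1.88 to 26.4), and fell in the blade from 27 to 2 counts, a ratio of 0.0542 (0.00625 to 0.216). Its fitted difference was 6.71 ± 1.05 (log2, SE; edgeR adjusted p = 0.00243) and ran from 5.63 to 10.80 over 33 refits. The 4 lamina joint counts at S1 all lay in the first library. Tag_001 fell in the lamina joint from 3703 ± 2020 CPM (SD, n = 2) to 224 ± 103 CPM (SD, n = 2), and its blade means were 162 ± 7.64 and 116 ± 52.3 CPM (SD, n = 2). Its fitted difference was -3.54 ± 0.82 (log2, SE; edgeR adjusted p = 0.0211). It did not pass the threshold (edgeR adjusted p up to 0.122) without the first lamina joint S1, the second blade S5 or any lamina joint S5 or blade S1 library, with fitted differences between -4.21 and -3.00 (SE 0.81 to 1.02) in those fits. The count of 17 from the F test was 31 without the second lamina joint S1 library and 3 to 11 without any other library except the first of lamina joint S1 and the first of blade S3. The other count of 17 was 27 without that library and 3 to 6 without any of the other 7 libraries of S1 and S5.

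**Figure D3:**
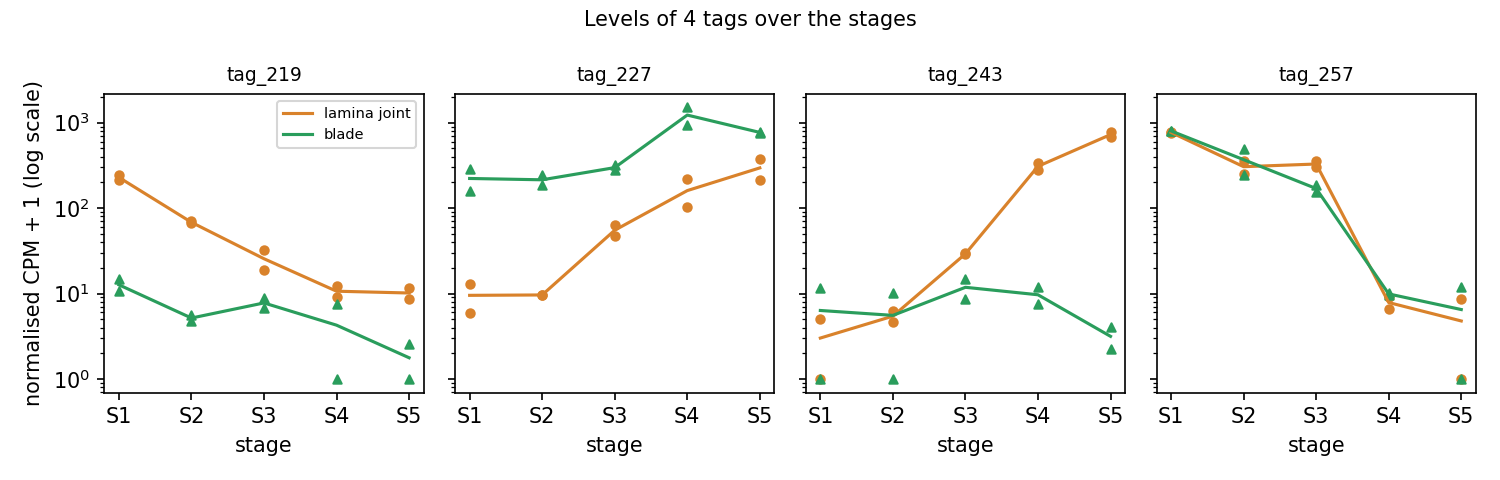
Normalised CPM plus 1 on a log axis against stage for tag_219, tag_227, tag_243 and tag_257; points are single libraries (circles lamina joint, triangles blade) and lines join group means. Tag_243 reached 723 CPM in lamina joint S5 and 2.16 CPM in blade S5, while tag_257 fell in both tissues.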

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

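Of the tests in this part, the comparisons with the blade S1 and lamina joint S5 replicates, the comparisons of shares and expected counts for library depth and the count without both second S1 libraries were chosen only after the result was seen. The course over the stages differed between the tissues for 17 tags by the F test of tissue by stage, and for 17 tags by the test of the difference between the S1 to S5 changes. The fitted differences, lamina joint minus blade on the log2 scale, were 10.39 for tag_243, 6.71 for tag_116 and -3.54 for tag_001. The value for tag_116 ran from 5.63 to 10.80 over 33 refits. Without the first blade S1 library tag_243 fell to 5.54 with an edgeR adjusted p of 1.00. Tag_001 lost its call without any of 6 single libraries of S1 or S5, while its fitted difference stayed between -4.21 and -3.00 (SE 0.81 to 1.02, against 0.82 with all libraries), and it reversed in 0 of 33 refits. Without both second S1 libraries the second count was 21. Groups of 2 libraries are too small for a test of single outlying samples.

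The second lamina joint S1 library differed from the first by more than 16-fold in 11 tags, 10 of them higher and 1 lower, against 0 to 6 such tags between the replicates of the other groups. The 10 higher tags held 0.0497% of the 516624 counts of the first library (95% Wilson interval 0.0440 to 0.0562). In the second library they held 2.55% (2.49 to 2.61) of 248416 counts. The 1 lower tag had 90 counts in the first library, or 43.3 expected in the second from the ratio of totals (95% Poisson interval 34.8 to 53.2). There 0 were seen (upper limit 3.69). These tags were picked for a gap over 16-fold after scaling for depth, so both comparisons restate that pick. They cannot decide whether library depth contributed, and the intervals do not allow for the pick. A condition shared by the second libraries of S1 remains open: 10 of the 11 tags differed in the same direction between the blade S1 replicates, with a median log2 difference of 3.44, against 0.18 between the lamina joint S5 replicates. RNA of another group mixed into the library stays open too. Of the 10 higher tags, 2 lay above their level in all other 18 libraries, which mixing alone would not give, but the rest did not. Those 18 included the second blade S1 library, which shared the deviation, so the rest do not decide about mixing. No biological explanation was tested, since replicates have no group of their own.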

How the results depend on the processing

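Fits without both second S1 libraries or without the most abundant tag were chosen after the data were seen. No printed tag reversed in 504 refits, and 496 kept it past the threshold. These tags were picked from the same data for large changes or small p, so reversals were unlikely beforehand. Many of the refits left out a library of a group outside the contrast, and merging identical tags could not alter the fit. Tag_656 in the blade had an adjusted p of 0.0519 without the first blade S1 library. In the difference between tissues, tag_243 had a fitted value of 5.54 and an adjusted p of 1.00, the highest of its refits, without that library. Tag_001 had adjusted p values up to 0.122 without the first lamina joint S1, the second blade S5 or any lamina joint S5 or blade S1 library. Counts for the average tissue difference (68 to 93 without leaving out single libraries), any stage difference (129 to 185 lamina joint, 122 to 156 blade) and S5 against S1 (123 to 147 and 126 to 161) stayed within 1.5 times the main count in each setting run. Without both second S1 libraries the tissues differed in 68 tags, and S5 from S1 in 136 and 126.

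For the other counts the cause of a change was not tested. For tissue by stage (17), DESeq2 size factors gave 7, no filter 52, DESeq2 39 and limma-voom 11. For the difference between S1 to S5 changes (17), DESeq2 size factors gave 11. Between tissues, no filter gave 35, 20, 25 and 26 tags at S1, S3, S4 and S5, and fits to the 4 libraries of a stage 1, 12, 21 and 3. DESeq2 gave 15, 13 and 22 at S3 to S5. At S4 limma-voom gave 10, and total counts or leaving out the most abundant tag 5. At S3 leaving out both second S1 libraries gave 16. With each library left out in turn, the counts between tissues ran from 13 to 25 at S1, 21 to 50 at S2, 0 to 15 at S3, 1 to 6 at S4 and 1 to 16 at S5. Tissue by stage ran from 3 to 31 and the difference between S1 to S5 changes from 3 to 27. The 0 came without the second lamina joint S3 library, where 36 tags had an unadjusted edgeR p under 0.05. A group left with 1 library was assumed to vary like the others.

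Replicate numbers were not taken to pair the samples: same-numbered deviations correlated above 0.1 in 13 of 45 pairs of groups (median -0.00216, lowest -0.265). The highest, 0.564, was that of lamina joint S1 with blade S1. Most of the 45 pairs cross stages, so their median cannot decide whether the tissues were paired within a stage. With the number as a block, counts were 83 for the tissues on average, 19, 45, 6, 4 and 12 at S1 to S5, 155 and 128 for any stage difference (lamina joint, blade), 128 and 147 for S5 against S1, and 15 and 17 for the tests between tissues. None moved by over 1.5 times. The block was a single term over all stages and cannot model pairing of the tissues within a stage. Merging identical tags removed 18, with 299 still tested. The tested tags were therefore unchanged, and this setting could not alter the main fit. The alternative of 1 tag per miRNA family and the set tests were not run, because the files do not pair tags with names. At this depth, with 2 libraries per group, 38.3% of simulated 4-fold changes between tissues at S5 were recovered.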

Other observations

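The tests of consecutive stages, of the best matching stage, of abundance classes in DESeq2 and limma-voom and of leaving out the most abundant tag were chosen after the results were seen. The count of tags past the threshold differed between steps from one stage to the next, and such counts also depend on depth. Blade S2 had the lowest mean total of any group, 294614 counts, against 707871 in blade S4 and 1036600 in blade S5. A low count for a step does not show that little changed. The blade means on the leading principal component were -13.43 at S1, -7.82 at S2 and -0.33 at S3. From S3 to S4, 53 tags changed in the lamina joint (27 higher, 26 lower) and 33 in the blade (9 higher, 24 lower) by edgeR's quasi-likelihood test, adjusted within each of 8 steps. With each library left out in turn these counts ran from 27, without the second lamina joint S4 library, to 59, and from 8, without the second blade S4 library, to 40. The S3 to S4 lists shared 8 tags that rose in both tissues, against 0.813 for independent lists, and 19 that fell in both, against 2.09, while 0 changed in opposite directions. In the lamina joint, 13 tags changed from S1 to S2, 28 from S2 to S3 and 8 from S4 to S5, and with each library left out these counts ran from 0 to 33, 0 to 36 and 1 to 17. In the blade, 25 tags changed from S4 to S5 (6 to 29 with each library left out), and no tag passed the threshold in edgeR from S1 to S2 or from S2 to S3, where 24 and 28 had an unadjusted p under 0.05.

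Differences between tissues on average were called in each class of abundance from 10 CPM up. Of the 48 most abundant tested tags, 16 differed between tissues on average, 5 higher in the lamina joint and 11 lower. Of the next 100 tags, down to a mean of 100 CPM, 38 differed, and of the 139 tags between 10 and 100 CPM, 28 differed. Of the 12 tags under 10 CPM, 0 passed the threshold in edgeR, with 0 at an unadjusted p under 0.05, 1 in DESeq2 and 3 in limma-voom. For the average difference between tissues as a whole, 1 of 100 splits of the libraries within stages, the real split itself, gave as many as 82 tags. The highest of the others gave 49, and their median was 0. Chance is thus argued against only as far as 100 splits can show. Most splits put both tissues into a group, which widens the spread and lowers the calls. The splits also do not reach beyond these libraries, whose replicates may be technical.

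Lamina joint libraries lay earlier than blade libraries of the same stage along a shared stage axis, drawn from mean S1 to mean S5 over both tissues and scaled to 100%. This axis was not among the tests fixed beforehand, and the leading principal component had already shown the same order of the tissues. The permutation of tissues covers only these libraries, whose replicates may be technical. The mean offset was -13.7% of the axis (exact permutation of tissues within stages, two-sided p = 0.000514; the smallest the 7776 arrangements can give is 0.000257), and both lamina joint libraries lay below both blade libraries at 4 of 5 stages. It was uneven, at -12.45% for S1, -23.0% for S2, -21.5% for S3, -3.75% for S4 and -7.90% for S5. Differences in library depth and the most abundant tags are argued against as its cause, since the offset was -14.1% with each library thinned to 194799 counts and -13.76% without the 10 most abundant tags. A lag of the lamina joint behind the blade may contribute. The best correlated blade stage of the 6 lamina joint libraries of S2 to S4 was on average -0.67 stages away. It was earlier for the 4 libraries of S2 and S3 and the same for the 2 of S4. For the blade libraries of S2 to S4 the best lamina joint stage was on average 0.333 stages later. That stage was lamina joint S3 for both libraries of blade S2 and of blade S3. The first blade S1 library, outside that range, also matched lamina joint S3 best (Spearman correlation 0.940). The blade matches thus cannot tell a lag from lamina joint S3 being the closest match to early blade in general. Tissue differences that happen to point along the axis, or the way each tissue was dissected, remain open and untested.

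The split of S5 against S1 between rising and falling tags depended on the scaling. Total counts shifted the median fitted change against TMM by -0.79 in the lamina joint and -0.65 in the blade (log2), while the shifts with DESeq2 size factors or upper quartile factors ran from -0.42 to 0.32 over all contrasts. The rising share of the most abundant tag is a candidate cause: without it, total-count scaling shifted the medians by -0.39 and -0.24, which left 49.2% and 37.2% of the shifts. That setting gave 59 tags higher and 79 lower in the lamina joint and 55 and 88 in the blade. What remains without that tag was not explained, and a change in the total amount of miRNA between stages cannot be read from these counts.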
